A study of Mus musculus with 12 samples.

How the data were processed

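RNA was sequenced from 12 single follicles, 6 fresh and 6 vitrified, isolated from 16-day-old CD-1 mice. Per the labels, each follicle was enclosed in 0.5% alginate and grown for 8 days with 10 mIU/mL recombinant follicle-stimulating hormone, RNA was taken from the lysate of a single follicle with magnetic beads, and libraries followed a Smart-seq protocol. The submitters' processing notes name Bowtie2, HISAT2, Partek and DESeq2 and the mouse build mm10, with no version, role or order. The counting rule, its use of strand and the gene annotation are not given in the sources used here.

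The data analysed were 1 table of the authors' own comparison of vitrified with fresh follicles, with 11806 genes. Per the file headers, the authors deposited for each gene a total count, an unadjusted p-value, a step-up adjusted p-value, a signed fold change and a log2 fold change. The total count deposited by the authors is pooled over libraries, and only 0.237% of the totals are whole within 0.001, so they were not treated as raw counts. The deposited p-value column and the deposited log2 fold change column were used as given. The signed fold and log2 columns deposited by the authors differed by more than 1e-09 in 0 genes. An adjusted p is missing for 843 genes, which are those with a total of at most 59.44, while each gene from 59.45 upwards has one. The lowest adjusted p divided by the lowest p puts the number of genes adjusted by the authors at 11029, against 10963 adjusted values in the table, and Benjamini-Hochberg values recomputed over these 10963 genes differed by at most 0.598% from the deposited ones. Groups came from the sample titles. No column of values per follicle was used.

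The planned design was a count or limma model of 12 libraries, written before the data were examined. The table holds no value per follicle, so the plan gave way to the authors' test with a threshold of 0.05 on the adjusted p. For the same reason the planned distances within and between groups, oocyte against granulosa balance, genes detected, mitochondrially encoded share and total per follicle were not computed. A Wald statistic was derived for each gene as the normal quantile of its p with the sign of its fold change, the standard error as log2 fold change over that statistic, and the 95% interval from these. This assumes a two-sided normal test. The median derived standard error was 0.29 on the log2 scale, from 0.49 for totals under 100 to 0.20 above 1000. This error holds both counting error and the spread between follicles, which cannot be separated here, and single genes of high total had large errors, such as Cyp11a1 with 0.79 and Nr4a1 with 0.70.

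Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the derived statistics, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 of 33 lists with at least 5 tested members. Correlations between genes could not be estimated without values per follicle, so preset values of 0.05 and 0 were tried in their place. The immune and ovarian surface epithelium lists had 1 tested member each, the histone list 4 and the red blood cell and mitochondrially encoded lists 0, too few for a test. List medians were also set against those of 10000 random lists drawn from 20 bins of total. The lists, 34 reference genes and the rule for named genes were fixed before the data were examined. The rule took the 12 called genes with the largest change in each direction at a mean of at least 5 per library, taken from the pooled total because means per group are not given, leaving out predicted genes and ribosomal pseudogenes. It added the reference genes, of which 1 is not reported here, and up to 4 members of each described list with the lowest p. Genes outside the rule were chosen after their values were seen, in the results Calm2, Dazl, Gm10800, Gm10801, Gm21738, Gm28048 and the list members Ndrg1, Slc16a3, Ldha and Hif1a.

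Symbols were matched to GENCODE release 21 of the mouse (GRCm38, the assembly called mm10), by symbol for 11643 genes and by a single older symbol for 89, so that 99.4% had coordinates. The share of each gene's 50-base windows, taken every 25 bases, that occur in another gene's transcripts was computed from the same release with Python 3.11.15. The steps were tested on simulated data for vitrified against fresh with the 10963 real genes and their derived errors, over 20 simulations of 200 changed genes each. The adjusted p called 15.7% of 1.5-fold, 50.3% of 2-fold and 93.0% of 4-fold changes, and 4.58% of calls were unchanged genes. A hypoxia and glycolysis list lowered by 0.35 was called in 20 of the 20 simulations. That size lies near the list's median of -0.34 in the data, so smaller shifts were not tried and the recovery is no evidence for the list's shift. The mean number of lists called with no list lowered was 0. Simulated genes were independent, so correlation between genes was not tested there. Their p-values were computed from the same normal errors that generated the values. A low share of unchanged genes among calls thus follows by construction and does not test the deposited p-values. The shares of genes called also depend on the number and size of the simulated changes of single genes, which were set and not taken from the data. Alternatives comprised no filter on totals, recomputed adjustment, centring of fold changes on their median, a t distribution with 10 degrees of freedom, a total of at least 120 and, for lists, other correlations and statistics. Figures were drawn with matplotlib 3.10.9.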

Results

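Single mouse ovarian follicles were sequenced one by one after 8 days of growth in alginate, and follicles that had been vitrified, that is, cryopreserved by cooling into a glass-like state, were compared with follicles that had stayed fresh. The follicles came from 16-day-old CD-1 mice, an outbred stock. There were 6 libraries from fresh and 6 from vitrified follicles. The values analysed were those of the authors' comparison, which gives for each gene a total over the libraries, a fold change and its p-value, so that no level or depth per follicle is given here. The totals of the 11806 genes in the authors' deposited table summed to 23783958, with a median of 273 per gene (quartiles 118 and 687). Gm10800, a predicted gene on chromosome 2, held 29.8% of that sum in the authors' deposited table. Together with the predicted genes Gm10801 and Gm21738 it held 32.2%. Of the sequence windows of Gm10800, Gm10801 and Gm21738, 28%, 21.1% and 42.3% occur in another gene, so their counts are uncertain. Whether these counts come from follicle messenger RNA was not tested, so the sum is not a measure of it. Among follicle genes, the inhibin alpha subunit gene Inha came next with a total of 1121840, then the connexin 43 gene Gja1 with 548309. The labels do not say which follicles shared an animal, so the p-values are taken as if the follicles were independent. If follicles of a group came from few animals, the p-values would be too small. A difference between the groups could then also be one between animals. The 95% intervals given with log2 fold changes of single genes were derived from each deposited fold change and its p-value. Intervals given with medians of gene sets, or differences of such medians, came from resampling genes. Genes are not replicates, so those intervals do not measure the spread between follicles.

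The question set by the series was how far the transcriptome of vitrified follicles differed from that of fresh ones. A list of hypoxia and glycolysis genes fell as a group, and in the authors' deposited table the glucose transporter gene Slc2a1 was 3.50-fold and the hexokinase gene Hk2 3.29-fold lower. The axon guidance ligand gene Slit2 fell most clearly, 17.2-fold in the authors' deposited table. The high-density lipoprotein receptor gene Scarb1 rose 2.22-fold and the nuclear long non-coding RNA Neat1 rose 2.33-fold in the authors' deposited table. The hormone and gap junction genes of granulosa cells Inha, Inhba, Cyp19a1 and Gja1, had log2 fold changes between -0.02 and 0.10 in the authors' deposited table, none past the threshold.

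Of 10963 genes with an adjusted p in the authors' deposited table, 58 passed 0.05, with 27 higher and 31 lower in vitrified follicles, or 0.529% of the genes tested. A change of at least 2-fold was found for 35 of them in the authors' deposited table, 17 higher and 18 lower. At an unadjusted p under 0.05 there were 770 tested genes, where 548 would be reached by chance with no change at all. The median log2 fold change was -0.02, and 98.2% of the tested genes had a fold change under 2. A further 159 genes had a fold change of 2 or more without passing the threshold. The 95% interval lay wholly within 2-fold for 7572 genes, or 69.1% of those tested. That share was higher at higher totals, at 13.0% for genes with a total under 100, 60.9% from 100 to 300, 89.7% from 300 to 1000 and 90.7% above 1000, so a change of 2-fold was often not detectable in the genes of lowest total. The test behind the deposited p-values is not given in the sources used here. If they come from a normal distribution, a t distribution of 10 degrees of freedom in its place leaves 0 genes past the threshold, with a lowest adjusted p of 0.0642 and 498 genes at an unadjusted p under 0.05. That loss follows from its heavier tails over this many genes, as even Slit2, with the lowest deposited p, does not pass. Whether 10 degrees of freedom suit the authors' test is not known here, so the loss does not decide which calls hold.

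**Figure D1:**
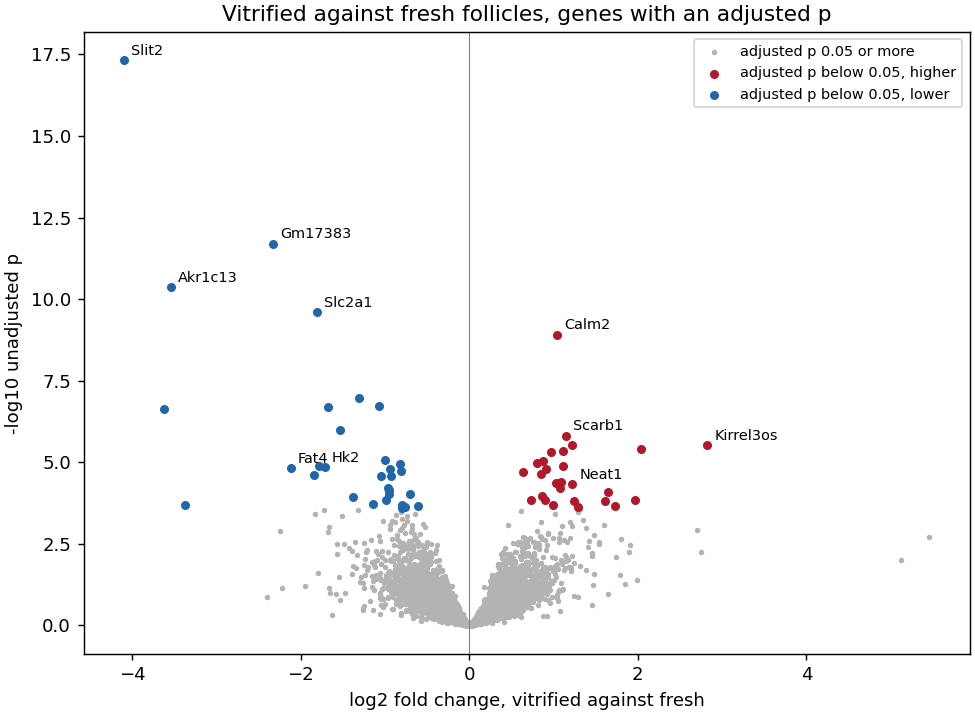
Each point is a gene with an adjusted p, placed by its log2 fold change (vitrified against fresh, x axis) and the -log10 of its unadjusted p (y axis). Red and blue points are the 27 genes higher and the 31 lower at an adjusted p under 0.05, and Slit2 lies farthest from the rest at a log2 fold change of -4.10.

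Among the genes that fell, Slit2, on chromosome 5 from 47983138 to 48307733 in GRCm38, had a log2 fold change of -4.10 (95% interval -5.03 to -3.17) and an adjusted p of 5.3e-14 in the authors' deposited table. The aldo-keto reductase gene Akr1c13, on chromosome 13 from 4191150 to 4205596, was 11.7-fold lower in the authors' deposited table (adjusted p = 1.6e-07), and 26.5% of its 50-base windows occur in another gene. Fat4, an atypical cadherin of planar cell polarity, was 4.35-fold lower in the authors' deposited table (adjusted p = 0.0068). BC034090 was 3.44-fold, the mitochondrial adenylate kinase gene Ak4 3.20-fold and the kinesin-associated scaffold gene Spag9 2.48-fold lower in the authors' deposited table. Aldh4a1, an enzyme of proline breakdown, was 2.20-fold, Tdrd5, a Tudor domain gene of the germ line, 2.11-fold and Tbl2 2.07-fold lower, and Plekha2, with a 95% interval of -1.44 to -0.56, had an adjusted p of 0.0053 in the authors' deposited table.

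Among the genes that rose, the antisense RNA Kirrel3os, on chromosome 9 from 34918233 to 34929509, had the largest change in the authors' deposited table at 7.07-fold, on a total of only 113, and its reads cannot be told from those of the opposite strand if counting ignored strand. Tmem181c-ps was 4.10-fold, AU021092 3.90-fold, H2-K2 3.31-fold, Zrsr1 3.14-fold and the amine oxidase gene Aoc3 3.05-fold higher in the authors' deposited table. The proteoglycan gene Bcan and Gch1, which makes the first enzyme of tetrahydrobiopterin synthesis, were 2.45-fold and 2.36-fold higher in the authors' deposited table. Neat1, on chromosome 19 from 5824708 to 5845478, had a log2 fold change of 1.22 (0.63 to 1.81) in the authors' deposited table, with an adjusted p of 0.015. Ubqln2, a shuttle factor of the proteasome, and the mitochondrial malic enzyme gene Me2 were 2.32-fold and 2.16-fold higher in the authors' deposited table. Calm2, a calmodulin gene chosen after its values were seen, had the lowest p of the genes that rose, at 2.06-fold and an adjusted p of 2.7e-06 in the authors' deposited table. In the rule for naming genes, 10 called genes with predicted names or ribosomal pseudogene names were passed over. Windows shared with another gene made up at least 50% of the sequence for 8 of 57 annotated called genes, among them Tmem181c-ps at 70.4%, and the counts of such genes are uncertain. That is 14.0% of called genes against 7.97% of all tested genes with coordinates (Fisher's exact test p = 0.13). The same limit holds for genes named below that were not called, Tuba1b at 82.4%, Tuba1a at 74.6%, Hspa1a at 65.8%, Bnip3 at 62.3% and Insl3 at 60.9%. Zrsr1 lies within the span of Gm28048, which was 10.4-fold lower in the authors' deposited table, so reads in the overlap are uncertain too.

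The hypoxia and glycolysis list fell as a group. Of its 31 tested members, 25 had lower and 6 higher values, with a median log2 fold change of -0.34, and the adjusted p of the list was 9.1e-09 (cameraPR, preset correlation 0.01). Of these members 3 fell at the adjusted p over all genes, and 7 fell when adjusted over the list alone. Slc2a1, on chromosome 4 from 119108711 to 119137983, had a log2 fold change of -1.81 (-2.37 to -1.25) and an adjusted p of 7.0e-07 in the authors' deposited table. Hk2 stood at -1.72 (-2.49 to -0.94), and Pfkfb3, which makes an activator of phosphofructokinase, at -0.99 (-1.50 to -0.48) in the authors' deposited table. The mitophagy receptor gene Bnip3 had a log2 fold change of -0.94 and an adjusted p of 0.11 in the authors' deposited table. The lactate exporter gene Slc16a3 stood at -0.92, Ndrg1 at -1.22 and Ldha, at a total of 91128, at -0.47 in the authors' deposited table, none past the threshold over all genes. Hif1a, which encodes the oxygen-regulated transcription factor itself, had a log2 fold change of 0.15 in the authors' deposited table (p = 0.52). Of the 20 tested members for glycolysis and glucose or lactate transport, 17 were lower, with a median of -0.26. Among the 11 other members 8 were lower, with a median of -0.44, so the fall was not confined to glycolysis genes. The difference between these parts was not tested. The list's median lay below those of all 10000 random lists matched on total. Random lists do not carry the correlation between genes of 1 pathway, so this comparison does not allow for it. With a preset correlation of 0.05 the adjusted p of the list was 1.6e-04.

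**Figure D2:**
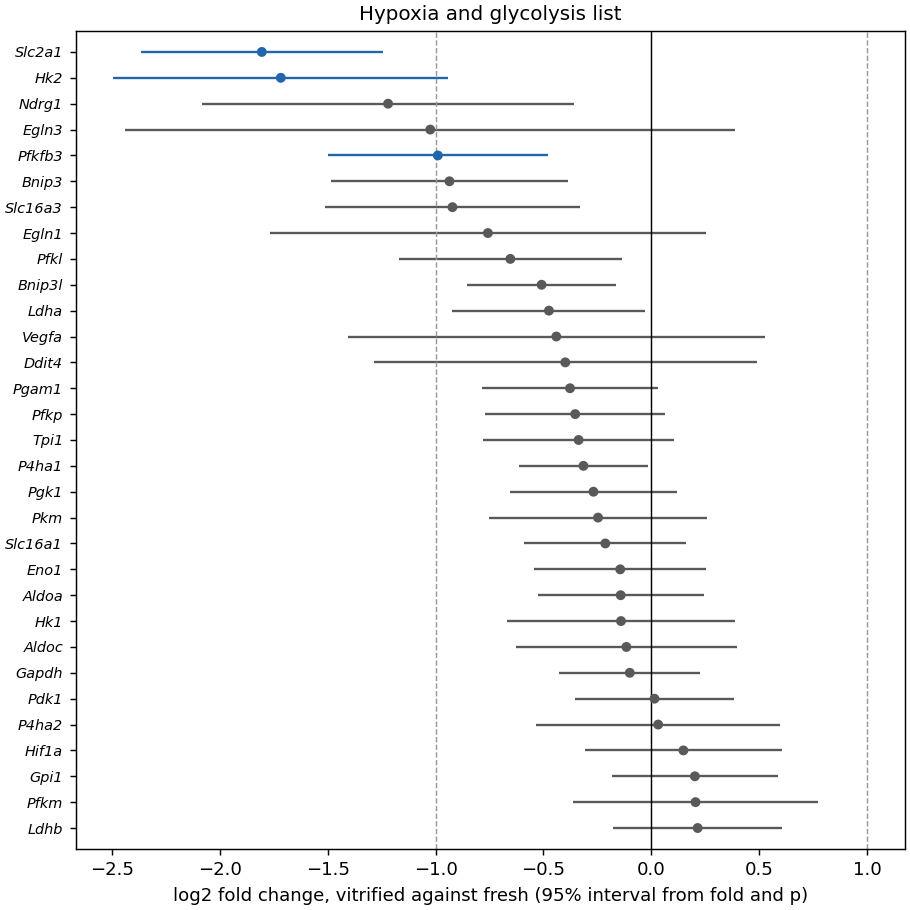
Points are the log2 fold changes of the 31 tested members of the hypoxia and glycolysis list (x axis, vitrified against fresh), with 95% intervals derived from fold change and p as lines and 2-fold marked by dashed lines. Slc2a1, Hk2 and Pfkfb3, in blue, pass an adjusted p of 0.05, and 25 of the 31 points lie below 0.

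The cell cycle list also fell as a group, with 38 of 44 tested members lower, a median log2 fold change of -0.27 and an adjusted p of 1.0e-04. None of its members passed over all genes or when adjusted over the list alone (0 in both), and 4 had an unadjusted p under 0.05. The replication licensing gene Mcm3 had a log2 fold change of -0.63, the cytokinesis gene Anln -0.84, the proliferation marker Mki67 -0.54 and the mitotic kinase gene Cdk1 -0.60 in the authors' deposited table. With a preset correlation of 0.05 the adjusted p of the list was 0.035.

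Immediate early genes, which respond within minutes to signals and handling, fell as a group, with 19 of 20 tested members lower, a median log2 fold change of -0.37 and an adjusted p of 0.0068. The count of members past the threshold was 0 over all genes and 3 when adjusted over the list alone, all 3 lower. These were the nuclear receptor gene Nr4a1 at -2.25 (-3.62 to -0.88), the salt-inducible kinase gene Sik1 at -1.25 and Klf6 at -0.76 in the authors' deposited table. The unfolded protein response list fell with 20 of 28 members lower and an adjusted p of 0.025, and the cytoskeleton list with 29 of 34 lower and an adjusted p of 0.046. Within them 0 members passed over all genes and 0 when adjusted over the list alone. The co-chaperone gene Dnajc3 had a log2 fold change of -0.38, Canx -0.33 and Xbp1 -0.34, and the tubulin genes Tuba1b and Tuba1a -0.56 and -0.42 in the authors' deposited table. The calls of these 3 lists were lost with a preset correlation of 0.05, at adjusted p = 0.077 for immediate early genes, adjusted p = 0.19 for the unfolded protein response and adjusted p = 0.20 for the cytoskeleton. The unfolded protein response call was also lost with log2 fold change in place of the statistic (adjusted p = 0.36), and the cytoskeleton call with log2 fold change (adjusted p = 0.090) and with no filter on totals (adjusted p = 0.056).

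The theca and oocyte lists, markers of other cells of the follicle, passed the test but kept their call in only 3 and 4 of 8 alternatives. The theca list rose, with an adjusted p of 0.046, but its members were split, with 8 of 14 higher and a median log2 fold change of 0.11. No theca member passed over all genes (0), and 4 passed when adjusted over the list alone, 3 higher and 1 lower. The theca and steroidogenesis lists share 4 tested genes. The retinaldehyde dehydrogenase gene Aldh1a1 had a log2 fold change of 1.19, the cholesterol transfer gene Star 1.60 and the hormone gene Insl3 2.70, against -0.50 for Fbln1, in the authors' deposited table. The oocyte list rose with 13 of 16 members higher, a median of 0.48 and an adjusted p of 0.046, but no member passed over all genes (0) or when adjusted over the list alone (0), and none had an unadjusted p under 0.05 (0). Zp2 and Zp3, of the zona pellucida, had log2 fold changes of 1.29 (-0.39 to 2.97) and 1.05 (-0.48 to 2.58), Padi6 1.24 and Oas1d 0.84 in the authors' deposited table. The oocyte list also holds 4 genes with no adjusted p, which were outside this test, among them the germ cell RNA-binding protein gene Dazl, chosen after its values were seen, at -2.14 (-3.56 to -0.73) in the authors' deposited table. With these included, in an alternative without a filter on totals that was also chosen after seeing the data, 15 of 20 members were higher and the call was lost (adjusted p = 0.13). Both calls were lost with a preset correlation of 0.05 (adjusted p = 0.19 for each list), at a total of at least 120 (adjusted p = 0.059 for theca and 0.081 for oocyte), after correction of the statistic for abundance, length and GC (adjusted p = 0.051 for each), and for theca also with ranks (adjusted p = 0.27) and without a filter on totals (adjusted p = 0.053). The granulosa list did not shift, with 9 members higher and 13 lower, a median of -0.04 and an adjusted p of 0.86. The endothelial list had 8 of 9 members lower, a median of -0.68 and an adjusted p of 0.11, but an adjusted p of 3.6e-07 with log2 fold change in place of the statistic (range over alternatives 3.6e-07 to 0.23).

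**Figure D3:**
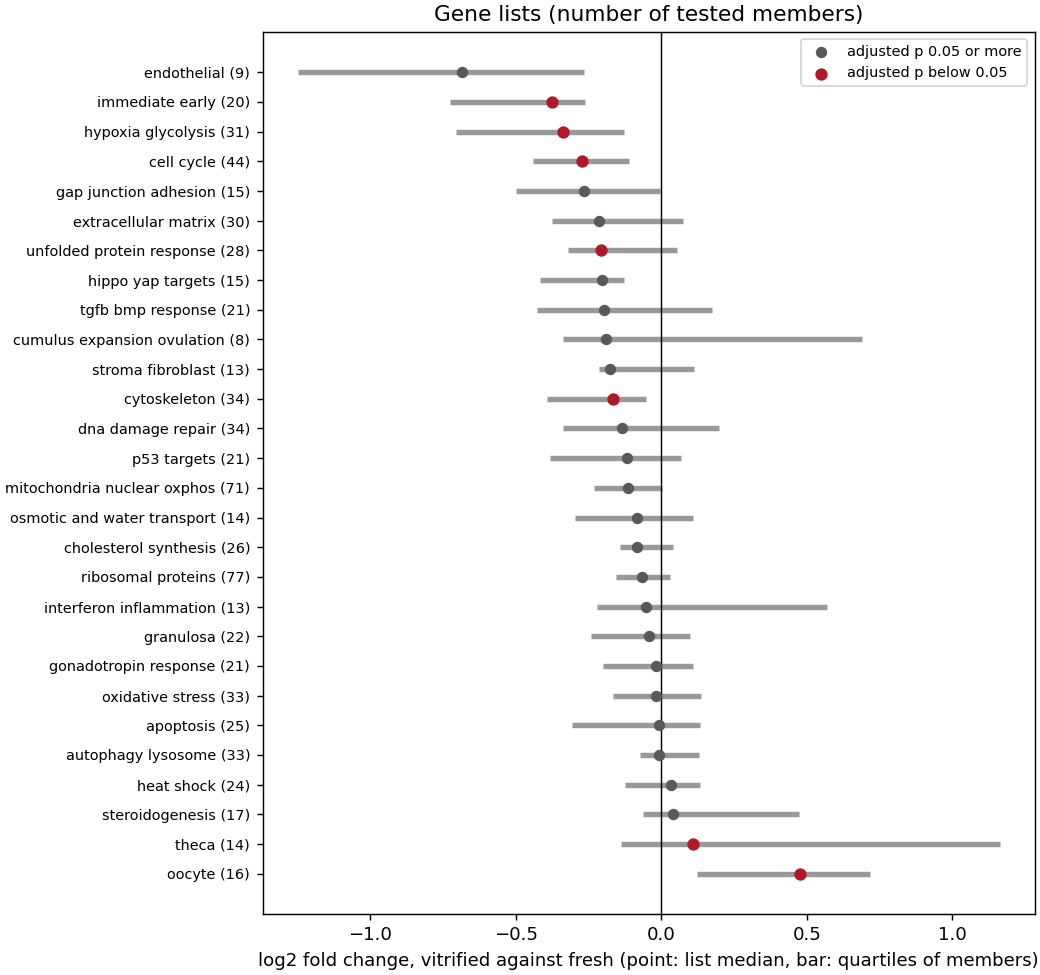
Each point is the median log2 fold change (x axis, vitrified against fresh) of a fixed gene list, with the quartiles of its members as a bar and the number of tested members beside its name. The 7 lists at an adjusted p under 0.05 are in red, 5 lower and 2 higher.

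Steroid synthesis genes as a list did not pass (adjusted p = 0.059), although Scarb1 rose, and 3 of 17 members, all higher, passed when adjusted over the list alone against 1 over all genes. Scarb1, which takes up cholesterol from lipoproteins, had a log2 fold change of 1.15 (0.68 to 1.62) and an adjusted p of 0.0015 in the authors' deposited table. Star and the ferredoxin gene Fdx1 stood at 1.60 and 0.67, with adjusted p of 0.11 and 0.21 in the authors' deposited table. The response genes of the TGF-beta and BMP pathway had an adjusted p of 0.059, with 13 of 21 lower. Targets of the Hippo pathway had an adjusted p of 0.080, nuclear genes of oxidative phosphorylation 0.083, gap junction and adhesion genes 0.10, and ribosomal protein genes and interferon and inflammation genes 0.25 each. DNA repair genes and p53 targets had an adjusted p of 0.49 each, autophagy and lysosome genes 0.56, extracellular matrix and oxidative stress genes 0.61 each, and cholesterol synthesis genes 0.69. Osmotic and water transport, cumulus expansion and stroma lists had 0.84 each, the heat shock, gonadotropin response and granulosa lists 0.86 each, and the apoptosis list 0.96. Over all genes and when adjusted over the list alone, these lists held 0 called members, except cumulus expansion, with 3 over the list alone, of which 1 was higher and 2 lower. The test was upward while the median was downward for the interferon (-0.05), autophagy (-0.01) and gonadotropin response (-0.02) lists, and the heat shock list was upward in median and test with a mean log2 fold change of -0.00061.

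Of the 31 reference genes fixed before the data were examined and found in the table, 30 were tested and 0 passed, and 3, Fshr, Star and Mki67, had an unadjusted p under 0.05. Their 95% intervals lay within 2-fold for 16. Inha had a log2 fold change of -0.02 (-0.33 to 0.29), Inhba 0.10 (-0.24 to 0.43) and Gja1 0.03 (-0.32 to 0.38) in the authors' deposited table. The aromatase gene Cyp19a1 stood at -0.02 (-0.52 to 0.48) in the authors' deposited table, and the sign for Inha and Cyp19a1 flips when fold changes are centred on their median. Fshr, the receptor of follicle-stimulating hormone, had a log2 fold change of 0.67 (0.14 to 1.20) and an adjusted p of 0.44 in the authors' deposited table. Star stood at 1.60 (0.66 to 2.53), Cyp17a1 at 1.47 (-0.04 to 2.97) and the side-chain cleavage gene Cyp11a1 at 0.47 (-1.08 to 2.03) in the authors' deposited table. The oocyte genes Gdf9 and Bmp15 had log2 fold changes of 0.43 and 0.58, and Nobox, with no adjusted p, 0.83 in the authors' deposited table. Kit and its ligand gene Kitl stood at 0.11 and 0.40, Lhcgr at 0.08, Foxl2 at -0.40 and Esr2 at -0.15 in the authors' deposited table. Gja4 had a log2 fold change of -0.68 (-2.07 to 0.70), Ccnd2 -0.41 and Cdkn1a -0.22 in the authors' deposited table. For the apoptosis genes Bax and Bcl2 the log2 fold changes were -0.50 and -0.46, and for the cold-inducible RNA-binding protein genes Cirbp and Rbm3 0.33 and 0.05 in the authors' deposited table. Hspa1a stood at 0.13, Hspa5 at -0.14, Ddit3 at 0.10, Sod1 at -0.17 and Sod2 at -0.14 in the authors' deposited table. The reference genes Ddx4, Amh and Aqp3 were not found among the 11806 genes, for a reason not known here, and so were not analysed.

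**Figure D4:**
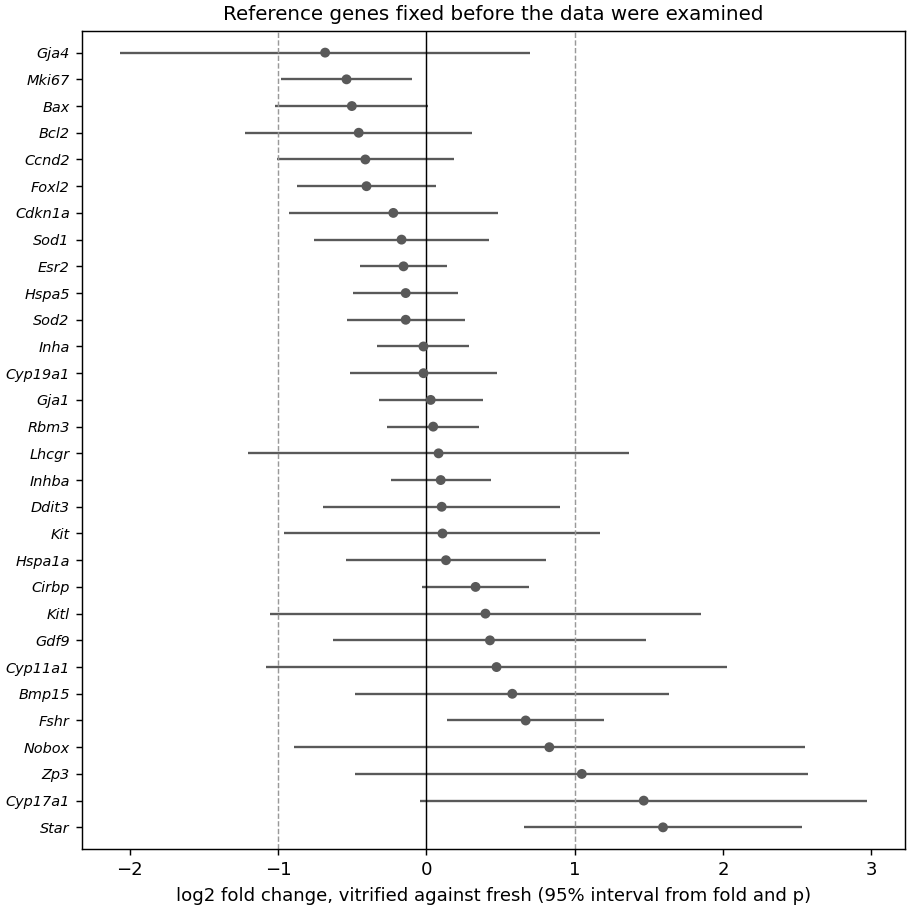
Points are the log2 fold changes (x axis, vitrified against fresh) of 30 of the 31 reference genes, with 95% intervals derived from fold change and p as lines and 2-fold marked by dashed lines. None passes an adjusted p of 0.05, Nobox having none, and Inha, Inhba and Gja1 have narrow intervals around 0.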

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

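The tests of neighbouring positions by chance and of dilution by other cells were chosen only after the result was seen.

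Gm10269, a processed pseudogene on chromosome 18, had a signal outside the genes tested. In the authors' deposited table it has no adjusted p at a total of 40.0, and its unadjusted p of 1.5e-04 lies below the highest p among called genes, 2.5e-04, with a log2 fold change of -3.85. Its derived 95% interval is -5.85 to -1.86, and 53.8% of its windows occur in another gene, so its count is uncertain.

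The hypoxia and glycolysis list was lower in vitrified follicles. A trend of the statistic with abundance, transcript length or GC content was removed by splines, and the list was still lower (limma cameraPR p = 1.2e-11, n = 30 genes, which are not replicates), which argues against that trend as the whole cause. Dilution of granulosa RNA by RNA of other cells would lower granulosa genes as much if the list's RNA came from granulosa cells. The list's median lay -0.30 (95% interval -0.49 to -0.06, by resampling genes) from that of the granulosa list. Of the granulosa list, 5 of 22 members had an unadjusted p under 0.05, in both directions. Which cells the list's RNA came from is not known here. The interval also does not measure the spread between follicles, so dilution is left open. Lists of other cells had medians of -0.68 (endothelial, 8 of 9 lower, adjusted p = 0.11, or 3.6e-07 with log2 fold change as the statistic and 3.6e-07 to 0.23 over alternatives), 0.48 (oocyte) and 0.11 (theca). Vitrification itself, a different oxygen supply or size of the follicles, a loss of cells of another type, and the animals of origin may each account for the pattern and were not tested.

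Long non-coding RNAs, a class chosen after their values were seen, were higher, with 154 of 234 tested genes above 0, a median log2 fold change of 0.20 and a limma cameraPR p of 1.3e-06, or p = 0.013 with a preset correlation of 0.05. After the same trend correction the class was still higher (limma cameraPR p = 5.3e-06, n = 234 genes). More unspliced RNA in the vitrified libraries would raise protein-coding genes with long introns. Their median lay -0.016 (-0.035 to 0.0066, by resampling genes) from that of genes with short introns. No rise of long-intron genes was thus seen, and the upper end is small beside the class median of 0.20. The interval reaches 0 and does not measure the spread between follicles, so more unspliced RNA is left open. Spliced RNA held in the nucleus was not covered by this comparison. No biological explanation was tested beyond the groups themselves.

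Called genes lay next to each other in 5 pairs within 500 kb, of which 4 pairs moved together, and 3 of the pairs come from Tmem181b-ps, Tmem181c-ps and Dynlt1b on chromosome 17. Chance placement gave as many pairs in a share of 0.02 of random draws. A change of whole neighbourhoods would carry their unique neighbours along, but these had a median signed log2 fold change of 0.014 (-0.26 to 0.17, by resampling genes), over 7 genes only. Reads shared between near-identical copies cannot be told apart from other causes, since the 7 genes ranged from 0 to 98.1% shared windows with a median of 43.8%. Differences in gene copies between outbred donor mice may also place called genes side by side and were not tested.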

How the results depend on the processing

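No paired analysis was possible because the table holds no values per follicle. For the same reason other normalizations and tools, pseudocounts, the stricter filter per sample, the oocyte covariate, estimated correlations, fry, leaving out follicles and other splits of the samples were not run. Of the alternatives, no filter on totals for genes and the 1.5-fold bound were planned, and the others, with no filter for lists among them, were chosen after seeing the data. Of the 58 called genes, 57 were also called with no filter on totals, 58 with a recomputed adjustment, 54 with fold changes centred on their median and 54 with a total of at least 120. The counts of higher, lower and 2-fold calls each went to 0 with a t distribution of 10 degrees of freedom, whose heavier tails are the cause by construction if the deposited p-values are those of a normal test. The 24 called genes among the 54 named ones compared all lost their call there. The share of genes bounded within 2-fold, 69.1%, became 64.1% with no filter, 23.2% for a 1.5-fold bound, 61.2% with the t distribution and 81.3% at a total of at least 120, by construction of the genes kept or the width asked. The 7 shifted lists became 2 with a preset correlation of 0.05 and 11 with 0, as the correlation sets the error of each list, 4 with no filter on totals, 5 with the trend-corrected statistic, 7 at a total of at least 120, and 8 each with ranks, with log2 fold change and without the called genes. Calls were gained by the endothelial (3.6e-07) and gap junction (0.022) lists with log2 fold change, steroidogenesis with log2 fold change (0.013) and correlation 0 (0.032), oxidative phosphorylation with correlation 0 (0.024) and ranks (0.030), Hippo targets with correlation 0 (0.049), ranks (0.030) and a total of at least 120 (0.048), and TGF-beta and BMP response with correlation 0 (0.031), a total of at least 120 and no called genes (0.048 each). The hypoxia and glycolysis and the cell cycle lists passed in all 8 list alternatives, with adjusted p up to 1.6e-04 and 0.035. The theca list passed in 3, the oocyte list in 4, immediate early genes in 7, the unfolded protein response list in 6 and the cytoskeleton list in 5. Signs reversed, without a call on either side, for Inha (adjusted p = 0.999) and Cyp19a1 (adjusted p = 1.00) on centring, by construction, as their log2 fold changes lie between the median of -0.02 and 0. They also reversed for the apoptosis (0.84), granulosa (0.92) and osmotic transport (0.83) lists at a total of at least 120, the apoptosis (0.99) and cumulus expansion (0.98) lists with no filter on totals, and the gonadotropin response list (0.97) with ranks, and the cause was not tested. The share bounded within 2-fold was lowest, at 13.0%, for genes with totals under 100, of which 1 was called, and the part of depth in this was not separated from the spread between follicles.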

Other observations

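The genes and regions here were chosen after their values were seen. A stretch of chromosome 17 from 6256860 to 6782784 held 8 genes of the table, all 8 higher in vitrified follicles, among them Dynlt1b at 2.11-fold, Tmem181b-ps at 2.13-fold and Dynlt1c at 1.99-fold in the authors' deposited table, the last without passing the threshold. Of these 8 genes, 7 share at least 10% of their windows with another gene, while Ezr, at 0, had a log2 fold change of 0.01 in the authors' deposited table. On chromosome 2 from 175129493 to 177206421, 20 of 23 genes of a zinc finger gene cluster were lower, with Gm14391 at -1.84 and Gm14308 at -1.53 past the threshold in the authors' deposited table, and all 23 share at least 10% of their windows. On chromosome 13, Akr1c13 and the neighbouring pseudogene Gm2123 were 11.7-fold and 12.3-fold lower in the authors' deposited table. H2-K2 was 3.31-fold higher while H2-K1, at 1.52-fold lower, did not pass in the authors' deposited table.

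Other called genes included the oxidoreductase gene Ero1l, 1.76-fold lower, the desaturase gene Scd2, 1.74-fold lower, the semaphorin gene Sema3c, 1.69-fold lower, and the histone demethylase gene Kdm4b, 1.52-fold lower in the authors' deposited table. The cytokine receptor gene Lifr was 2.04-fold and Rsrp1 1.96-fold higher in the authors' deposited table. Gm26917 was 2.16-fold higher in the authors' deposited table, and it ends 12 bases before the 18S ribosomal RNA pseudogene Rn18s-rs5 on chromosome 17. Malat1 had a log2 fold change of 0.59 and an adjusted p of 0.61 in the authors' deposited table. Gm17383, 5.04-fold lower in the authors' deposited table, shares 100% of its windows with another predicted gene and 64.2% with each of the tubulin genes Tuba1a and Tuba1b. Gm10925, at 0.32 in the authors' deposited table, shares 100% of its windows with the mitochondrial gene mt-Atp6. Processed pseudogenes as a class had 211 of 619 tested members higher, a median log2 fold change of -0.14 and an adjusted p of 0.0062 over 3 gene classes (limma cameraPR), and an adjusted p of 0.60 after correction for abundance, length and GC. With a preset correlation of 0.05 the class had a limma cameraPR p = 0.17 (n = 619 genes).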
